A study of Drosophila melanogaster with 3 samples.

How the data were processed

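The data were chromatin immunoprecipitation peak lists for Broad, a zinc finger transcription factor of the ecdysone response, tagged with eGFP and recovered from whole wandering larvae, in the third instar, of Drosophila melanogaster with an antibody against GFP. The labels describe transgenic flies expressing br-eGFP fusion proteins. They name the tagged form br-RE, and which zinc fingers this form carries was not established here. The labels give 1 group of 3 biological replicates, numbered 2, 3 and 4, of larvae of both sexes together. Chromatin was sonicated to a size range of 200 to 800 bp, per the labels. No group was set against another, so no comparison between conditions was made and none of the tests speaks of a difference between conditions.

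The authors deposited 1 ranked list of regions per replicate, which includes regions of background strength. They also deposited 1 list called on the 3 replicates pooled, and 1 list of peaks kept by an irreproducible discovery rate threshold, named optimal by the authors. Each list was deposited for the dm6 and the dm3 assembly, per the labels. The strength of a region is a signal value set by the authors' peak caller, and it was used to rank, filter or describe regions within 1 list. It was also correlated between replicates at matched regions, and set side by side between the dm6 and dm3 lists. The authors also deposited a −log10 q-value per region, which was used only to describe the lists. The aligner, the peak caller and the normalization are not given in the sources used here. The control library was not analysed here. Read depth is unknown, so no precision could be drawn from it, and intervals on shares of peaks cover counting error only.

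The main peaks were the 2533 optimal dm6 peaks. They were identical to the 2533 regions of highest signal in the pooled list of 27389 regions. Each replicate list held 30000 regions, and its 2533 strongest regions (the top regions below) gave a value per replicate, from which the mean and SD over 3 replicates were taken. Because the optimal list is the head of the pooled list, a peak in it need not be strong in each replicate.

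Genes and transcription start sites (TSSs) came from Ensembl release 115 on BDGP 6.54, and sequence from the RefSeq copy of the same assembly. All region ends lay within its chromosomes. Transposable elements and pseudogenes were left out. Coordinates are 1-based dm6 positions, and no coordinates were converted between assemblies. Of 373 listed symbols, 359 matched by symbol, 11 matched by synonym, and 3 were not matched.

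A region of one list was shared with another when the summits lay within 200 bp. Chance sharing came from 100 shuffles of summits within chromosomes. Location classes were assigned in a fixed order: within 1000 bp of a TSS (promoter), then 5′ UTR, 3′ UTR, coding exon, noncoding exon, intron and intergenic. They were compared with 1000 shuffles of summits within chromosomes, by a two-sided permutation test. Chromosome arms were compared with their assembled length by a two-sided exact binomial test. The relation of signal rank and promoter position was tested across peaks with 100000 permutations. A gene counted as bound when a summit lay within 1000 bp of any of its TSSs. Each of 24 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided. Sequence words were sought on both strands in windows reaching 100 bp to either side of nuclear summits, and in equal windows 1000 bp away on both sides. An exact McNemar test compared each summit with 1 flank drawn at random. The 17 words include an AP-1 word and its reverse complement, which give the same values. Genes with many peaks were those with more summits in the body plus 1000 bp than in 1000 shuffles, by an upper-tail permutation test over genes with at least 3 summits. Adjusted p-values are Benjamini-Hochberg values within each family, and intervals are exact 95% binomial intervals. Peaks, or genes for gene lists and genes with many peaks, are the units of these tests, so the p-values describe these lists. Genes of a list that lie side by side are not independent, which can make the p-value of such a list too small. The SD over replicates is the biological error.

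Lists, words, tests, alternatives and the rule for named genes were set before the data were examined. The text names br, the genes with the TSS nearest to the 25 strongest optimal peaks, the 15 protein-coding genes with the most summits, and of each list up to 4 bound members in order of signal plus up to 2 unbound members in list order. Renamed symbols were matched after the data were examined. Alternatives chosen after seeing the data were leaving out mitochondrial peaks, leaving out mitochondrial genes, random draws of regions as the chance level of sharing, a binomial test over all protein-coding genes for genes with many peaks, dinucleotide-preserving shuffles of the word windows, and 200 random subsets of the optimal peaks of the same size as each smaller peak set. The alternatives set beforehand changed the sharing rule (100 or 500 bp, regions overlapping by 1 bp or by 50% of each), the number of regions, the peak set, the promoter distance, the word windows, the gene limits and the shuffled space, and left out each replicate in turn. Leaving out a replicate meant keeping the optimal peaks found in the top regions of both others. Matched random lists were 10000 draws of genes with the same number of TSSs (with 4 or more as 1 class) and the same class of gene length, of 5 classes of equal size.

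The statistics were tested on simulated data. With 2510 summits placed at random 20 times, the shuffle test of genes with many peaks called 3.5 genes on average and at most 14, and the binomial test called 0 on average. These placements were even along each chromosome, as in the shuffles, so they do not cover the gathering of real summits at promoters. Of 480 list tests on these placements, 2 passed the threshold. All 30 genes given added summits were recovered, and a simulated shared share of 50% was measured as 50.5%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1 were used.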

Results

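Peaks of tagged Broad were mapped by anti-GFP chromatin immunoprecipitation in whole wandering larvae of the third instar. At this stage larvae leave the food before pupariation. The gene br encodes a family of zinc finger proteins induced early by the moulting hormone ecdysone. There was 1 group of 3 biological replicates, numbered 2, 3 and 4. The optimal list held 2533 peaks with a median width of 404 bp, and the authors' signal ran from 88.3 to 6030 within it. Read depth per replicate is unknown.

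The first question was how far the replicates shared their strongest sites. A pair of replicates shared 49.8% ± 0.726 (SD, n = 3 pairs) of the top 2533 regions. Replicates 2 and 3 shared 49.6%, replicates 2 and 4 shared 49.2%, and replicates 3 and 4 shared 50.6%. Shuffled summits shared 0.875%, and regions drawn at random from the replicates' own lists shared 3.02%. Across matched nuclear regions, which are not independent replicates, Pearson's r of the signal was 0.781, 0.711 and 0.781 and Spearman's rho was 0.566, 0.531 and 0.57 for these pairs. Of the optimal peaks, 966 (38.1%, exact 95% interval 36.2 to 40.1) lay in the top regions of all 3 replicates, 822 in those of 2, 672 in those of 1 and 73 in none. Of the strongest 25% of peaks 89.9%, and of the weakest 25% 1.58%, were found in all 3 replicates. The signal that ranks the peaks is pooled from these replicates and the top regions of each are cut at the same number, so a fall in support towards the foot of the list is largely expected. The share found in all 3 replicates rose to 82.1% when all 30000 regions of each list counted, and fell to 21.7% with 50% as many top regions.

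**Figure D1:**
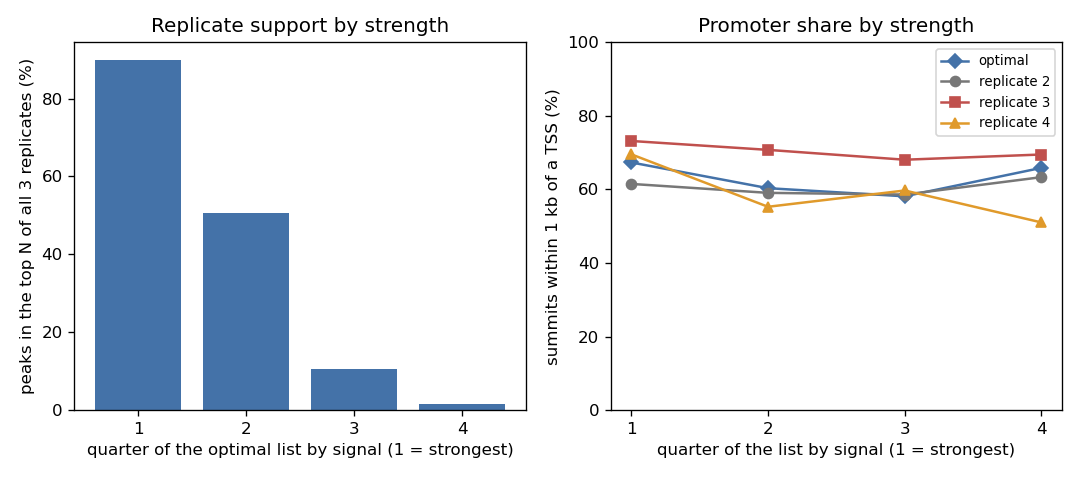
The left panel gives, for each successive 25% of the optimal list by signal, the percent of peaks found in the top regions of all 3 replicates, which runs from 89.9% in the strongest to 1.58% in the weakest. The right panel gives the percent of summits within 1 kb of a TSS in the same way for the optimal list and each replicate; in the optimal list the strongest 25% is at 67.4% and the weakest at 65.9%.

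Summits lay mostly at promoters, and few lay in coding exons or 3′ UTRs beyond them. Within 1 kb of a TSS lay 1594 optimal summits (62.9%, exact 95% interval 61.0 to 64.8), against 23.9% of shuffled summits, and the replicates' top regions gave 63.3% ± 6.19 (SD, n = 3). The other classes count only summits beyond 1 kb of any TSS, so exons within 1 kb of a TSS are part of the promoter class. Coding exons held 3 such summits (0.118% against 9.83% shuffled), and 3′ UTRs held 12 (0.474% against 4.17%). Introns held 26.4% against 35.8%, and intergenic sequence held 9.83% against 25.4%. The permutation p was 0.002 for each of these 5 classes, the smallest that 1000 shuffles can give (adjusted p 0.0028). Summits in 5′ UTRs were also fewer than shuffled (adjusted p 0.00466), and those in noncoding exons did not pass the threshold (adjusted p 0.0779). The median distance to the nearest TSS was 429 bp, against 3344 bp for a set of shuffled summits. In the replicates it was 498, 266 and 610 bp.

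**Figure D2:**
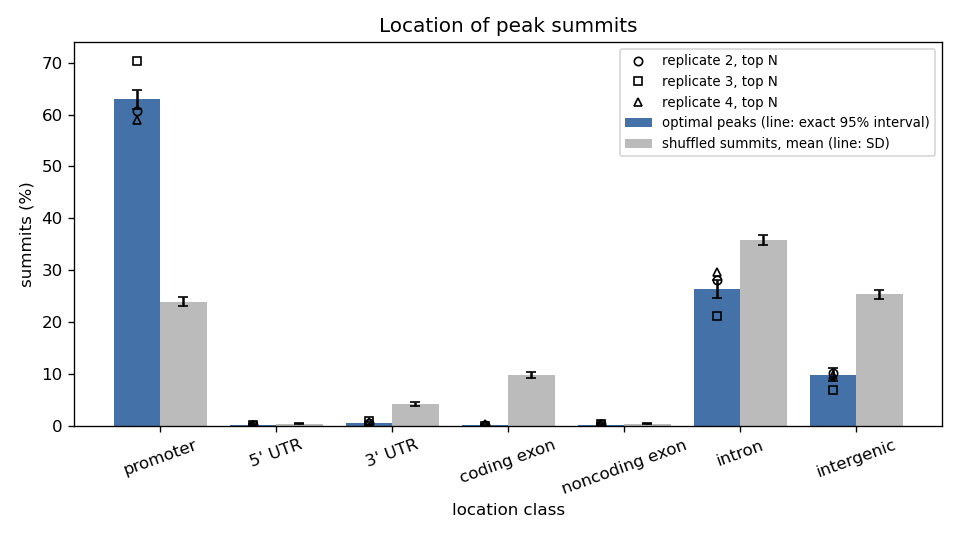
Percent of summits in each location class, where all classes but promoters lie beyond 1 kb of any TSS, for the optimal peaks (dark bars, lines are exact 95% intervals), for the top regions of each replicate (open symbols) and for shuffled summits (grey bars, lines are SD over 1000 shuffles). Promoters hold 62.9% of the optimal summits against 23.9% of the shuffled ones.

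Stronger peaks were not found at promoters more often in the optimal list. The promoter share was 67.4% in the strongest 25% of peaks, 60.3% and 58.1% in the next groups of equal size and 65.9% in the weakest, with Spearman's rho of 0.021 across peaks (permutation p = 0.292). The relation was positive in replicate 4 (rho 0.12, permutation p = 1e-05, the smallest that 100000 permutations can give) and in replicate 3 (rho 0.0435, permutation p = 0.0282), but not in replicate 2 (rho −0.0129, permutation p = 0.518). It passed the threshold among peaks found in all 3 replicates (rho 0.0949, permutation p = 0.00331) and among the upper 50% of peaks by signal (rho 0.0855, permutation p = 0.00246). It also passed without replicate 3 (rho 0.15) and without replicate 4 (rho 0.1), but not without replicate 2 (rho −0.0107). Mitochondrial regions within 1 kb of an annotated TSS count as promoter peaks here, and they held the top rank in replicates 2 and 3. Of the 2533 top regions, 2513, 2501 and 2533 were nuclear in replicates 2, 3 and 4. The small rho of replicate 3 was taken with the mitochondrial regions included and may rest in part on them.

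Peaks were spread over the large arms nearly by length, with few on chromosome 4 and none on Y. Chromosome 4 held 8 of the nuclear peaks, 0.325 times its share of length (exact binomial test, adjusted p 0.000787), with 0.199%, 0.68% and 0.553% of the top nuclear regions in replicates 2, 3 and 4 against 0.98% of length (0.487 ± 0.254 times, SD, n = 3), and Y held 0 (adjusted p 5.44e-29); how well reads can be placed on Y was not analysed here. Arm 2L held 482 peaks, 1.12 times its share (adjusted p 0.0136), and this call was lost without replicate 2 (adjusted p 0.153). The X chromosome held 424 peaks, 0.987 times its share (adjusted p 0.791), with 15.4%, 14.1% and 21.2% of the top nuclear regions in replicates 2, 3 and 4. Without replicate 3 the X share was 19.6%, above its share of length (adjusted p 0.0447). Arms 2R, 3L and 3R did not differ from their length (adjusted p 0.513, 0.513 and 0.199).

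Of the 25 strongest peaks, 8 were mitochondrial and 17 nuclear. The mitochondrial ones were nearest to the TSSs of mt:CoI, mt:ND5, mt:tRNA:Gly-TCC, mt:tRNA:Lys-CTT, mt:tRNA:Leu-TAA, mt:tRNA:Leu-TAG and mt:tRNA:Ser-TGA, and no mitochondrial region was listed in replicate 4. All 17 nuclear ones lay in the top regions of all 3 replicates, at rank 59 or better in each. The strongest nuclear peak (2L, 480905 to 481282) lay in an intron of ush, 1362 bp from the TSS of cbt, and ranked 11, 21 and 3 in replicates 2, 3 and 4. Next came a peak 96 bp from the TSS of CG14100 (3L, 19590449 to 19590787) and one 31 bp from the TSS of Ugalt, which encodes a UDP-galactose transporter (X, 2703717 to 2704068). Another lay in the promoter of ph-p, which encodes a Polycomb group protein (X, 2137188 to 2137523, ranks 32, 26 and 6). Further strong promoter peaks lay at CG1888, PNPase, Lk6, CenG1A, gish and larp. Strong introns and intergenic sites included those nearest to CG11050, CG16753, CG32772 and CG13323, the last 11923 bp from its TSS, and 3 peaks were nearest to the noncoding genes lncRNA:CR44619, lncRNA:CR46035 and lncRNA:CR31044.

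The br locus itself (X, 1575132 to 1664869, plus strand) held 4 optimal peaks, of moderate strength and uneven support. The promoter peak (1574273 to 1574676) ranked 1212 in the optimal list and 317 in replicate 2, and no region of replicates 3 or 4 had a summit within 200 bp of it. By this peak br counts as bound among the ecdysone response genes below. The other 3 peaks were intronic, at 1578004 to 1578407 (rank 1028), 1578243 to 1578646 (rank 1248) and 1595759 to 1596162 (rank 1216). The peaks of rank 1028 and 1248 overlap and had the same counterparts in replicates 3 and 4, at ranks 4362 and 1750. The peak of rank 1248 also had a counterpart in replicate 2, at rank 716, whereas that of rank 1028 did not. The peak of rank 1216 had none in replicate 3.

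The next question was which groups of genes carried peaks at their promoters. Signal at open promoters in general was not separated from Broad binding, since the control library was not analysed. Of 13981 protein-coding genes 1898 (13.6%) were bound, and the replicates gave 13.4% ± 2.43 (SD, n = 3). Of the 24 lists, 3 were bound more often than other genes and 1 less often, and 7 had an unadjusted p below 0.05. The list of Trl and other broadly bound chromatin factors led, with 11 of 16 bound (68.8%, 5.09 times other genes, adjusted p 7.63e-06). Among them were ph-p, the insulator protein gene Cp190 (rank 339), the remodeller gene brm (rank 350) and lola (rank 430), but not pho or Pc. Replicates 2, 3 and 4 had 10, 10 and 8 of the 16 bound. Of the ecdysone response genes 14 of 27 were bound (51.9%, 3.84 times, adjusted p 1.46e-05). The strongest were the nuclear receptor gene Eip75B (rank 266), Ldh (rank 427), the transporter gene E23 (rank 642) and the ETS factor gene Eip74EF (rank 877), while Eip78C and Hr4 had no promoter peak. In their bodies plus 1 kb, Eip78C held 2 summits and Hr4 held 6. With promoters of 500 bp the share fell to 33.3% and the list still passed (adjusted p 0.0147). Replicates 2, 3 and 4 had 12, 11 and 7 bound, and in replicate 4 the list did not pass (adjusted p 0.319). The call was also lost without replicates 2, 3 and 4 in turn, where 18.5%, 11.1% and 18.5% were bound against 7.37%, 5.98% and 6.84% of other genes (2.51, 1.86 and 2.71 times), and among the peaks found in all 3 replicates (11.1% against 5.23%, 2.12 times, adjusted p 0.766). These sets hold 966 to 1248 of the 2533 peaks. Random subsets of the optimal peaks of the same size, chosen after seeing the data, bound 22.4% to 28.1% of the list on average, and the list was below them without replicate 3 (permutation p = 0.0199) but not in the other sets (permutation p from 0.169 to 0.309).

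Of the cytosolic ribosomal protein genes 34 of 85 were bound (40%, 2.98 times, adjusted p 3.14e-08), with 25, 31 and 24 in replicates 2, 3 and 4. RpL34b (rank 287), RpL32 (rank 359) and RpL7 (rank 401) had summits within 131 bp of a TSS, whereas the peak assigned to RpS19b (rank 241) lay 896 bp upstream of it. This call held without replicate 3 (15.3% bound against 5.94% of other genes, adjusted p 0.0153) and without replicate 4 (18.8% against 6.79%, adjusted p 0.00363). It was lost without replicate 2 (10.6% against 7.37%, 1.44 times, adjusted p 0.745) and among the peaks found in all 3 replicates (10.6% against 5.21%, 2.03 times, adjusted p 0.35). Random subsets of the same size bound 20.3% and 16.3% of the list on average, so that the list was below them without replicate 2 (permutation p = 0.00995) but not among the peaks found in all 3 replicates (permutation p = 0.0896). Odorant and gustatory receptor genes, active in sensory neurons, were bound at 1 of 119 (0.84%, adjusted p 8.9e-06), the exception being Or9a, with 1, 1 and 0 in replicates 2, 3 and 4. Genes matched on number of TSSs and gene length were bound at 22.6% for the chromatin list, 23.9% for the ecdysone response list, 14.1% for the ribosomal list and 11.5% for the receptor list. All 4 lists passed against matched genes as well (adjusted p 0.0032, 0.0132, 0.0024 and 0.0024).

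Heat shock genes were bound at 6 of 17 (35.3%) and did not pass (adjusted p 0.0973), with Hsp27 at rank 71. Replicates 2 and 3 had 9 and 8 bound and passed (adjusted p 0.000156 and 0.0131), whereas replicate 4 had 4 bound and did not (adjusted p 0.389). With promoters of 500 bp, and with the upper 50% of peaks, the list passed (adjusted p 0.0459 and 0.0358). Autophagy genes were bound at 6 of 20, led by Atg17 (rank 496) and Atg2 (rank 1012), with an adjusted p of 0.152 and 4, 6 and 5 bound in replicates 2, 3 and 4. They passed with promoters of 2000 bp (40% bound, adjusted p 0.0443). Of the cell death genes 2 of 17 were bound, the inhibitor gene Diap1 (rank 216) and the activator gene hid (rank 301), but not rpr or grim (adjusted p 1), whereas replicates 2, 3 and 4 had 5, 4 and 2 bound (21.6% ± 8.99, SD, n = 3). The juvenile hormone list had 2 of 12 (Jheh1 and Jheh2, not Kr-h1 or Met), the clock list 3 of 12 (sgg, vri and cry), the neuroblast list 3 of 15 (brat, Syp and grh), the leg and wing list 2 of 14 (RhoGEF2 and sqh) and the neuronal list 1 of 13 (elav), with adjusted p of 0.807, 0.396, 0.668, 1 and 1. In replicates 2, 3 and 4 the juvenile hormone list had 2, 3 and 3 bound, the clock list 4, 4 and 3, the neuroblast list 5, 3 and 2, and the neuronal list 1 in each. The leg and wing list had 5, 3 and 4 (28.6% ± 7.14, against 13.3% ± 2.44 of other genes, SD, n = 3), and did not pass in any replicate (adjusted p 0.0629, 0.536 and 0.319). The imaginal disc list had 3 of 31 (Dll, Egfr and sd, adjusted p 0.905). It had 8 of 31 in replicate 2, 0 in replicate 3 and 1 in replicate 4 (adjusted p 0.0642, 0.0255 and 0.319). When the whole gene body counted, 35.5% of it was bound and the list passed (adjusted p 0.049). That count makes no allowance for gene length, and longer genes take more summits by chance.

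Many lists of tissue genes had no member with a promoter peak. These were the salivary glue and 71E puff genes (0 of 22, adjusted p 0.188), such as Sgs1 and Sgs3, the cuticle and pigment genes (0 of 30, adjusted p 0.11), such as Lcp1, the fat body storage protein genes (0 of 9, adjusted p 0.783), such as Lsp1alpha, and the muscle genes (0 of 15, adjusted p 0.396), such as Mhc. The ecdysteroid synthesis (0 of 15), testis (0 of 19), midgut (0 of 17), chorion (0 of 17), haemocyte (0 of 13), tracheal (0 of 9) and Hox (0 of 8) lists had adjusted p from 0.26 to 0.783. None of these 11 lists passed. The larvae were taken whole, and the optimal peaks are only the strongest regions of the pooled list. Binding confined to a small part of the larva may fall below that cut, which was not tested. A list with no bound member therefore does not show that Broad is absent from its genes in their own tissue. The same limit holds for the odorant and gustatory receptor genes above. Peaks away from promoters do not count here: ush, of the haemocyte list, had no promoter peak but held 8 summits in its body plus 1 kb. The cuticle list did pass with promoters of 2000 bp (0% bound, adjusted p 0.0298) and in replicate 3 (0 of 30, adjusted p 0.0351). It also passed when the whole gene body counted, with no allowance for gene length (0% bound, adjusted p 0.0216). Many genes of the cuticle list lie side by side, so these p-values can be too small. Replicates 2 and 4 had 0 and 1 of its 30 genes bound, and replicates 2, 3 and 4 had 2, 1 and 1 of the 15 muscle genes.

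**Figure D3:**
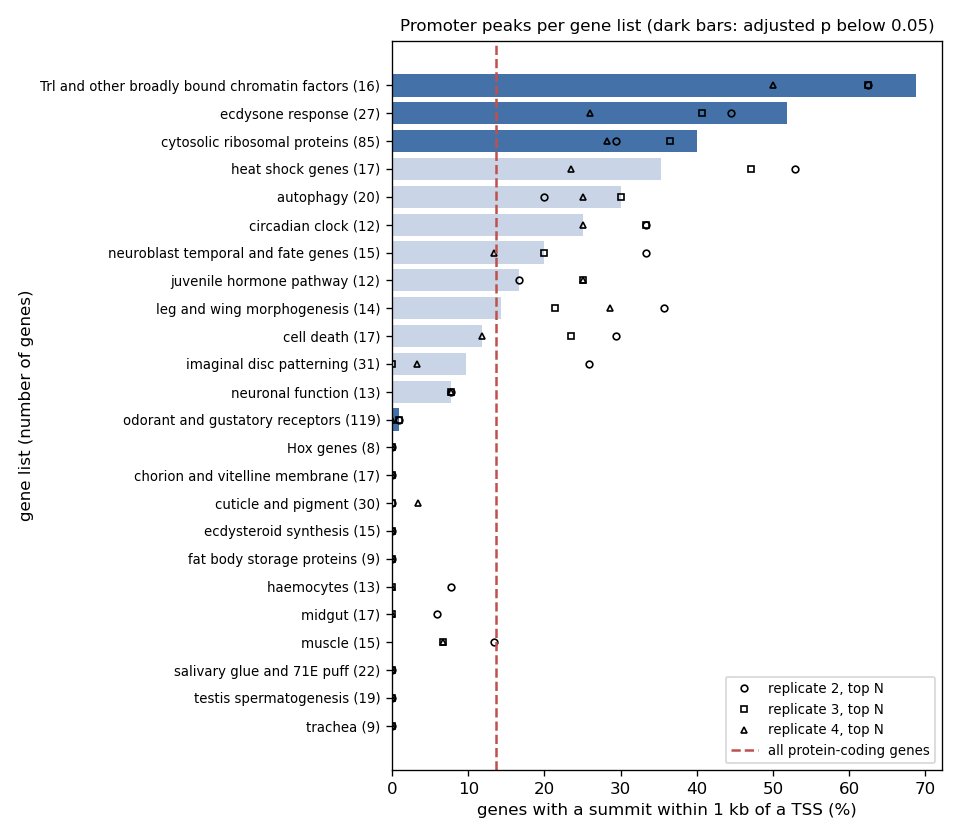
Percent of the genes in each list with an optimal summit within 1 kb of a TSS (bars, dark where the adjusted p is below 0.05) and with a top region of each replicate there (open symbols). The dashed line marks all protein-coding genes at 13.6%. The list of broadly bound chromatin factors reaches 68.8% and that of ecdysone response genes 51.9%.

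Sequence words at nuclear summits were compared with flanking sequence. The word TATCGATA, the core of the DNA replication-related element, was in 3.31% of summit windows against 0.558% of flanks, a ratio of 5.93 (exact McNemar test, adjusted p 2.38e-11), and its replicate ratios were 5.47 ± 3.87 (SD, n = 3). It was concentrated at promoters: 80 of 1573 promoter summits and 3 of 937 other summits held it. The Broad words of isoforms Z2 (CTATTT), Z3 (AAACTA) and Z4 (GTAAACA, also the forkhead core) were at 1.36, 1.43 and 1.43 times their flank share (adjusted p 1.04e-06, 1.77e-08 and 0.0029), and A tracts at 1.40 times (adjusted p 5.99e-05). Summit windows were richer in A and T than flanks, with 36.6% against 43.0% G and C, and dinucleotide-preserving shuffles of the same windows gave ratios of 1.43, 1.5 and 1.5 for these 3 Broad words. The Z1 word was not enriched (ratio 0.936, adjusted p 0.575). Which zinc finger isoform carried the tag was not established here, so none of the Broad words could be taken as that of the tagged protein. The word GGTCACAC, known as an M1BP site, was at 2.11 times (adjusted p 0.0029), and AGGTCA, a core word that the ecdysone receptor shares with other nuclear receptors, fell below its flanks at 0.643 times (adjusted p 0.0029). Both calls were lost among the upper 50% of peaks and without any one replicate (adjusted p from 0.0841 to 0.847 without a replicate), and that of the Z4 word was lost without replicate 3 (adjusted p 0.909). The GAGA repeat (1.26) and the CA repeat (0.841) did not pass (adjusted p 0.416 and 0.495), nor did the words for Zelda, AP-1, Grainyhead, GATA factors or the E-boxes. The replicate ratios were 1.4 ± 1.04 for the GAGA repeat and 0.954 ± 0.591 for the CA repeat (SD, n = 3), each with 1 replicate above 1. The GAGA repeat passed with flanks 2000 bp away (1.44, adjusted p 0.0177). The CA repeat fell below its flanks without replicate 2 (0.514), without replicate 3 (0.574), among the peaks found in all 3 replicates (0.518) and in windows reaching 50 bp to either side (0.557). Dinucleotide-preserving shuffles were not run for AGGTCA, the M1BP word or the CA repeat. Base composition was therefore not weighed for the fall of AGGTCA and the CA repeat below their flanks.

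**Figure D4:**
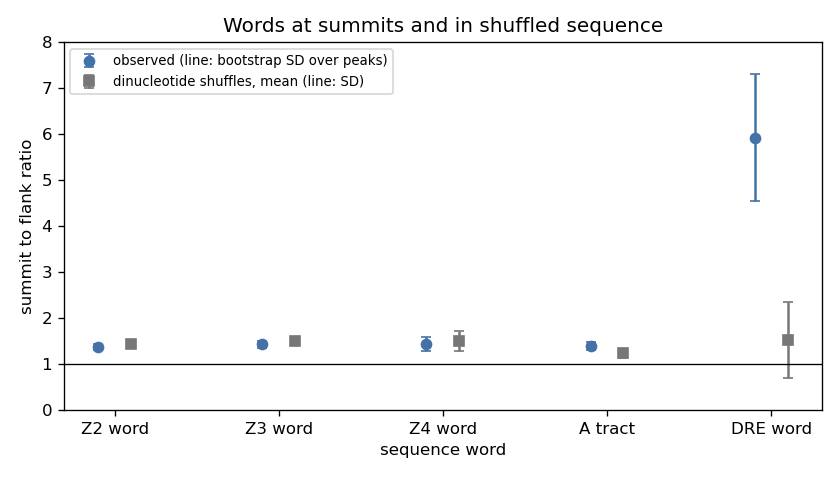
Summit to flank ratio of 5 words as observed (circles, lines are bootstrap SD over peaks) and in dinucleotide-preserving shuffles of the same windows (squares, lines are SD over shuffles). The 3 Broad words lie at 1.36, 1.43 and 1.43 against 1.43, 1.5 and 1.5 in the shuffles, and the DRE word lies at 5.93 against 1.53.

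Some genes held more Broad peaks than shuffled positions gave. Of 173 genes with at least 3 summits, 131 passed the permutation test, and 22 passed a binomial test over all protein-coding genes, which does not first select genes by their summits. Both tests place summits evenly along each chromosome, whereas 62.9% of optimal summits lay within 1 kb of a TSS against 23.9% of shuffled ones. The counted stretch of every gene holds its TSSs, so passing can reflect the gathering of summits at promoters, which neither test allows for. Tlk, which encodes a chromatin-linked kinase, held 13 summits against 1.34 expected and sbb held 11 against 1.45, and both passed under both tests. CHES-1-like, a forkhead gene, held 10 against 0.525, tara held 8 against 0.702, Raf held 8 against 0.905, osa held 7 against 0.591 and brat held 7 against 0.95, and these passed both tests too. Replicates 2, 3 and 4 had 16, 6 and 6 summits in Tlk, 14, 14 and 11 in sbb, 9, 6 and 8 in CHES-1-like, 13, 5 and 9 in tara, 9, 5 and 9 in Raf, 10, 4 and 4 in osa and 7, 6 and 7 in brat. None of tara's 8 summits lay in the top regions of all 3 replicates. Eip75B held 10 against 2.15 (adjusted p 0.00412, binomial adjusted p 0.0531), and it held 3 without replicate 2 and 3 without replicate 4, where the call was lost. CG43658, ush, tai, heca, CG1677 and Mur2B held 7 to 9 summits and passed the permutation test alone. The gene body of Mur2B overlaps br. Mur2B held fewer than 3 summits when each replicate was left out in turn, and its call was lost. The long gene kirre held 11 against 7.19 and did not pass (adjusted p 0.133).

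The dm3 lists of the same data gave a similar picture on the nuclear chromosomes. The optimal list held 2437 peaks in dm3, and 19.2%, 17.4%, 21.0%, 24.9% and 17.1% lay on arms 2L, 2R, 3L, 3R and X, against 19.0%, 17.6%, 21.0%, 24.4% and 16.7% in dm6. Mitochondrial peaks numbered 5 in dm3 and 23 in dm6, and the strongest of them ranked 632 in dm3 (signal 178) and 1 in dm6 (signal 6030), whereas the strongest nuclear signal was 1297 and 1298.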

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

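The tests of the mitochondrial and of the dm3 explanation, and those on tissue genes and tRNA genes, were chosen only after the result was seen. Those of base composition and of closely spaced promoters were chosen after the patterns were seen, with their predictions written before the test results. Mitochondrial regions were not part of the comparisons by arm, and their number stood out. Replicate 2 listed 23, replicate 3 listed 36, the optimal list held 23, and replicate 4 listed 0. Regions touched 100% of the 14 bins of 1 kb before the A+T-rich part of the mitochondrial chromosome in both replicates 2 and 3 in dm6, as recovery of mitochondrial DNA along its whole length would give, but 57.1% and 50% in dm3, which leaves this open. A property of the dm6 mitochondrial sequence alone is argued against as the cause of all of these regions, since the dm3 lists of replicates 2 and 3 held 8 and 9. It is not excluded for their strength: the strongest mitochondrial signal in dm3 was 97.8 against 4485 in dm6 for replicate 2 (2.18%) and 154 against 1365 for replicate 3 (11.3%), while the strongest nuclear signal in replicate 2 was 590 in both, and why the builds differ was not tested. Why replicate 4 listed none stays open, and no biological explanation was tested.

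The AT-rich Broad words at summits were weighed against base composition. Dinucleotide-preserving shuffles gave as high a ratio for the Z2, Z3 and Z4 words, with the observed ratio 0.62, 0.667 and 0.264 combined SD below the shuffled one (differences of −0.62, −0.667 and −0.264). Base composition is thus enough to give the excess of the Z2 and Z3 words over their flanks. For the Z4 word the spread is too wide to decide (bootstrap SD 0.155, SD over shuffles 0.212). It was in 6.375% of summit windows against 4.53% of shuffled ones, and in 4.44% of flanks against 3.04% of shuffled ones. For A tracts the observed ratio was 1.27 SD above the shuffled one, which leaves base composition open. For the DRE word it was 2.73 SD above, which argues against base composition as its cause. No group in the design gives a biological explanation to set against these.

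Peaks at promoters of ribosomal protein genes were weighed against 3 explanations. Abundant transcription stays open: 0 of 76 glue, storage, cuticle and muscle genes were bound (Fisher's exact test, p = 2.77e-05), but these lists were pooled after each had been seen with 0 bound, and transcript levels in these larvae were not analysed here, so the test decides nothing. Signal at accessible genes in general stays open too: 10 of 167 tRNA genes away from protein-coding TSSs were bound (5.99%), against 4.59% of protein-coding genes with 1 TSS as far from others (Fisher's exact test, p = 0.351), a comparison chosen after all protein-coding genes (13.6%) had been used and found to differ in their number of TSSs. Closely spaced promoters are argued against, since lists matched on neighbouring TSSs had 15.9% bound on average and 30.6% at most, against 40% (permutation p = 0.0001, the smallest that 10000 lists can give). Signal at open promoters, which a control library or an untagged strain would measure, was not analysed here, and no biological explanation was tested.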

How the results depend on the processing

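The alternatives without mitochondrial peaks, without mitochondrial genes, with random draws and with a binomial test over all genes were chosen after seeing the data, as were the dinucleotide-preserving shuffles of the word windows and the random subsets of peaks; the others were planned. The promoter, intron, intergenic and coding exon shares and the low counts on chromosome 4 and Y kept their direction and side of the threshold under every alternative run, and the top regions of the pooled list moved nothing because they are the optimal peaks. The percent shared by a pair of replicates was 43.9 at 100 bp, 52.5 at 500 bp, 52.0 with regions overlapping by 1 bp, 45.0 by 50% of each, 56.0 in the top N/2, 44.2 in the top 2N and 32.6 over all regions, and 49.2 to 50.6 when leaving out one replicate. The percent of optimal peaks found in every replicate was 33.2, 40.2, 27.9 (50% of each), 21.7 (top N/2), 60.4 (top 2N) and 82.1 (all regions), and 48.6 to 49.3 when leaving one out, where 2 replicates rather than 3 must hold the peak. Chance sharing was 3.02% with random draws. The rho of rank and promoter position was 0.0855 in the upper 50% of peaks, 0.0949 in peaks found in all 3 replicates, and −0.0107 to 0.15 leaving one out. The ecdysone response list was bound at 22.2% in the upper 50% of peaks (adjusted p 0.055), 11.1% in peaks found in all 3 replicates, 33.3% at 500 bp (adjusted p 0.0147), 63% at 2000 bp, 70.4% with the gene body plus 1 kb, and 11.1% to 18.5% leaving one out; the upper 50%, all-replicate and leave-one-out sets hold 966 to 1266 peaks, and random subsets of the same sizes bound 22.4% to 28.1% of the list on average and passed in 65% to 75% of draws. Lists bound more often numbered 1 in peaks found in all 3 replicates, 6 with the gene body plus 1 kb, and 1 to 2 leaving one out; lists bound less often numbered 2 at 2000 bp and 2 with the gene body. The imaginal disc list went from below other genes, without passing, to above them at 35.5% with the gene body. Counts over the gene body make no allowance for gene length. Words above their flanks numbered 3 in the upper 50% of peaks and 2 over 1 kb from any TSS, and words below numbered 0 and 0 there, and 0 to 1 leaving one out. The call of the DRE word was lost over 1 kb from any TSS, where the ratio was 0.546 and rested on few windows. There 3 of 937 summits held the word, with 3 discordant peaks towards the summit and 4 towards the flank. Genes with many summits numbered 48 in the upper 50% of peaks, 36 in peaks found in all 3 replicates, 81 with the body only, 22 by the binomial test, and 46 to 56 leaving one out. Mur2B fell to 0 and tara to 0 summits in peaks found in all 3 replicates, and Mur2B held 0 to 2 leaving one out. Arm 2L was at 19.1% to 20.7% and X reversed within 16.8% to 19.6% leaving one out. Among single lists, words, genes and minor classes, 540 values kept their side of the threshold, 51 lost it, 14 gained it and 6 reversed. The 540 include the values for the top regions of the pooled list, which could not change. They also include values that changed direction but passed in neither setting. A value counted as reversed when its direction changed and it passed in either setting. The cause of the other changes was not tested. Unknown read depth limits what a region missing from a replicate means. No paired analysis was possible because there was 1 group.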

Other observations

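The test of the hypothesis below was set before its result was seen, whereas the comparison of pairs with independent promoters and the 8-base words were chosen after. Outside protein-coding genes, promoter peaks were at snoRNA genes (20 of 269, 7.43%), nuclear tRNA genes (19 of 290, 6.55%), snRNA genes (2 of 32, 6.25%) and ncRNA genes (220 of 3289, 6.69%). They were at 0 of 99 nuclear rRNA genes, against 13.5% of nuclear protein-coding genes and 4.54% of those with 1 TSS and no head-to-head partner. These groups were not compared by a test. The replicates gave 6.81% ± 2.81 for snoRNA genes, 7.93% ± 3.84 for tRNA genes and 6.73% ± 0.544 for ncRNA genes (SD, n = 3).

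Among all 8-base words in at least 40 summit windows, CTGAGAGA had the highest summit to flank ratio, 11, with 8.91 ± 2.02 (SD, n = 3) in the replicates. The overlapping words TGAGAGAA, ACTGAGAG and CACTGAGA followed at 9.5, 8.75 and 7.74. CACTGAGA was in 5.87% of the 937 summits away from promoters against 0.427% of their flanks (exact McNemar test, p = 1.7e-12), and in 2.16% of the 1573 promoter summits against 0.477% (p = 2.53e-05). These p-values are for a word picked for its ratio in the same peaks and are too small for that reason. The words CTGAGAGA and TGAGAGAA share the run GAGAGA with the listed GAGA repeat word, GAGAGAG. No factor was assigned to any of these words.

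A hypothesis of this work was that head-to-head promoters carry Broad peaks more often. Of 5052 nuclear genes with an opposite-strand TSS up to 1000 bp upstream, 1212 were bound, against 673 of 8916 other genes (7.55%), and the replicates gave 22.5% ± 5.17 against 8.07% ± 0.951 (SD, n = 3). Among genes with 1 TSS the shares were 20.1% and 4.54%, and the larger p of both Fisher's exact tests was 4.73e-130, which is too small because partner genes share peaks. Part of the difference follows from construction, since 1 window then covers the promoters of both genes. Taken as units, 565 of 2216 pairs (25.5%) held a peak at either promoter, against 14.5% expected of 2 independent single promoters (exact binomial test, p = 1.09e-41). The hypothesis is consistent with these counts, and open chromatin at such promoters may give them as well, which was not analysed here.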
